A study of Mus musculus with 2 samples.

How the data were processed

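Leukocytes from the aorta of Apoe-/- mice were profiled by droplet-based single-cell 3' RNA sequencing (10x Genomics, on an Illumina NovaSeq), with 1 library from saline-treated and 1 from nt-LNA-treated mice. How many mice went into each library is not given in the sources used here. Cell Ranger 2.1.1, Seurat and the mouse build mm9 are named in the submitters' processing notes. Filters on cells, the settings of the clustering and any removal of doublets are not given in the sources used here.

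The deposited counts are whole-number unique molecular identifiers (UMIs) per gene, summed over the cells of each of 20 clusters with both libraries pooled. They hold 31053 genes, of which 19560 had at least 1 count. A second deposited table holds, per its values, log2(count + 1) multiplied by 1 factor per cluster, so that the upper quartile over all genes was 4.35 in every cluster. The factors ran from 0.602 to 2.74. These values are treated as a score, because their differences are not log2 fold changes, and they were used only to read the authors' scaling. A deposited table of cells gives the library, cluster and cell type name of each cell. A deposited summary gives, per the file headers, the number of cells (counts), the percent of cells per library rounded to 1 decimal, a cell type score and a p-value for the cell type name of each cluster. The scale of that score and the test behind that p-value are not given in the sources used here, and neither was used further. Tallies of cells from the cell table equalled those of the summary (largest difference 0).

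Gene symbols were used as the count table gives them. Of these, 30464 (98.1%) matched gene names of GENCODE M21. That annotation uses another build than the one in the submitters' notes, so no coordinates are given.

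Because the counts pool both libraries within each cluster, the treatments were compared only by the share of each library's cells in each cluster. The gene comparisons between treatments that had been planned, over all cells, within clusters and by gene list, are not analysed here. Shares carry exact Clopper-Pearson 95% intervals, ratios of shares exact conditional 95% intervals, and CPM, the count scaled to the total of its cluster, exact Poisson 95% intervals. All these intervals cover counting error only, not differences between animals or libraries. With 1 library per treatment no test was made and no p-value was computed.

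Expression was compared between clusters on CPM, computed here from the deposited counts by dividing by the cluster's total. The ratio for a gene is its CPM in a cluster over the mean CPM of the other clusters. For a gene with 0 counts elsewhere, the reference was 3 counts over the total of the other clusters. The log2 ratios of gene lists used a pseudocount of 0.5 CPM and members with at least 20 counts. For 22 gene lists the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 50 bins, with the percentile as a description of these libraries. The clusters were made from the same expression values, so their genes describe the clusters and are not tested.

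The comparisons, gene lists, cell type markers and rule for named genes were set before the data were examined. For each cluster the rule takes the 10 genes with the largest ratio among those with at least 50 counts. For each list it takes the 2 members with the largest absolute log2 ratio and the 2 with the most counts. It always includes Apoe, Tlr7, Tlr8, Tlr9, Tlr13, Il1b, Tnf, Trem2, Spp1, Lyve1, Ccr2, Ly6c2, Cd3e and Ptprc. A gene may be named outside the cluster in which the rule chose it. Xist, Malat1, the Y-linked genes, Cd8a, Cd8b1, Dntt, Rag2, Ptcra, Arpp21, Aqp11 and Gata6 were named after the values of other genes, or their own, had been seen.

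A cluster was called X-like when at least 3 markers of 1 cell type were among its 50 leading genes and no other marker list had as many among the leading 10. This scoring rule was chosen after the data were seen. The clusters with the fewest UMIs per cell (2, 5 and 16) also needed at least 1 such marker among their leading 10. Because the deposited names Macrophages, T cells and B cells cover clusters led by markers of other types, clusters were compared by number. No doublet caller was run, since it needs counts per cell, which are not used here.

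The calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated counts for cluster 10 against the other clusters, over 31053 genes with 50 genes changed at each size. All simulated clusters shared the same pooled profile, with genes drawn independently, apart from the changed genes in cluster 10. The real clusters differ in cell type, and genes of a list may vary together. The simulation therefore checks the calculations and does not calibrate the list percentiles for these data. True folds of 2, 4, 8 and 0.25 were recovered with medians of 1.95, 3.86, 7.72 and 0.257. All 50 genes raised 8-fold were among the 50 leading genes, and 5.5% of unchanged lists fell in the top or bottom 2.5%. The Poisson and ratio intervals were checked apart from these simulated clusters, in draws at fixed means. They covered the true value in 96.1% and 96.3% of draws. Alternatives tried were other denominators for shares, scaling by the upper quartile, other count minimums, other reference clusters and another rule for naming clusters.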

Results

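The study asked how nt-LNA affects which cells are present in the atherosclerotic aorta and what state they are in. LNA is the usual abbreviation of locked nucleic acid, a sugar-modified nucleotide used in antisense oligonucleotides. Apoe-/- mice lack apolipoprotein E, accumulate cholesterol-rich lipoproteins and develop atherosclerotic plaques. They ate a western diet for 4 weeks and received weekly saline or 30 mg/kg nt-LNA. Live cells that carried CD45, a surface protein of leukocytes, and lacked CD3, a part of the T cell receptor complex, were sorted from the digested arch and thoracic aorta. There was 1 library per treatment (n = 1). The saline library held 2742 cells and the nt-LNA library 4871. Together the 7613 cells yielded 70206506 UMIs, a mean of 9222 per cell, and the totals of the 20 clusters ran from 212515 to 12985745. UMI totals per library are not analysed here.

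Cells of 2 myeloid clusters, 7 and 10, were less frequent in the nt-LNA library than in the saline library. Cluster 7, a neutrophil-like cluster, held 8.28% of the saline library (95% interval 7.27 to 9.37) and 3.26% of the nt-LNA library (2.78 to 3.80). Cluster 10 had 3 markers of foamy, lipid-laden macrophages among its 50 leading genes and a monocyte marker among its leading 10. By the mean log2 ratio of each marker list it was classical monocyte-like instead. It held 7.62% (6.66 to 8.68) of the saline library and 3.06% (2.59 to 3.58) of the nt-LNA library. The ratios of nt-LNA to saline shares were 0.394 (0.320 to 0.485) and 0.401 (0.323 to 0.498). The mature dendritic cell-like cluster 8 held 6.78% of saline and 3.88% of nt-LNA cells, a ratio of 0.572 (0.465 to 0.704). Among the clusters deposited as Macrophages without cluster 6, a choice made after the data were seen, the cluster 8 ratio was 0.882 (0.717 to 1.09).

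Among the other myeloid clusters, the nonclassical monocyte-like cluster 15 held 2.19% of saline and 1.48% of nt-LNA cells, a ratio of 0.676 (0.473 to 0.968). Cluster 0, the largest, was rich in complement transcripts and held 13.1% of saline and 11.9% of nt-LNA cells, with a ratio of 0.913 (0.799 to 1.04). With B, T and NK cell clusters left out of the denominator, its ratio turned to 1.28 (1.12 to 1.47) and that of cluster 15 to 0.951 (0.665 to 1.36). The type 1 dendritic cell-like cluster 17 had a ratio of 0.880 (0.580 to 1.35) and the plasmacytoid dendritic cell-like cluster 18 one of 1.10 (0.625 to 1.99). Cluster 19 held 5 saline and 22 nt-LNA cells, a ratio of 2.48 (0.915 to 8.37).

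Lymphoid and cycling clusters went both ways. For the proliferating-like cluster 6, which carried T lineage genes, the ratio was 1.14 (0.940 to 1.39). The B cell-like cluster 1 held 12.7% of saline cells and 7.62% of nt-LNA cells, a ratio of 0.600 (0.517 to 0.697). Cluster 2, which also carried B cell genes, went the other way, with a ratio of 1.84 (1.53 to 2.21). Together the 4 clusters deposited as B cells (1, 2, 4 and 12) held 26.8% and 31.2%, a ratio of 1.16 (1.06 to 1.27). The NK cell-like cluster 3 held 9.70% and 7.43%, a ratio of 0.766 (0.652 to 0.901). The plasma cell-like cluster 4 held 6.20% of saline cells (5.33 to 7.17) and 9.30% of nt-LNA cells, a ratio whose interval ran from 1.25 to 1.80. Its name rests on 4 marker genes, so these are shares of the cluster and not of plasma cells. Cluster 11, with genes of group 2 innate lymphoid cells (ILC2-like), had a ratio of 1.43 (1.12 to 1.84). The B cell-like cluster 12 and the unnamed cluster 13 had ratios of 1.71 (1.27 to 2.31) and 1.53 (1.15 to 2.06). With all cells in the denominator, the interval lay above 1 for 7 clusters (2, 4, 5, 11, 12, 13 and 14), below 1 for 6 (1, 3, 7, 8, 10 and 15) and held 1 for the other 7.

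**Figure D1:**
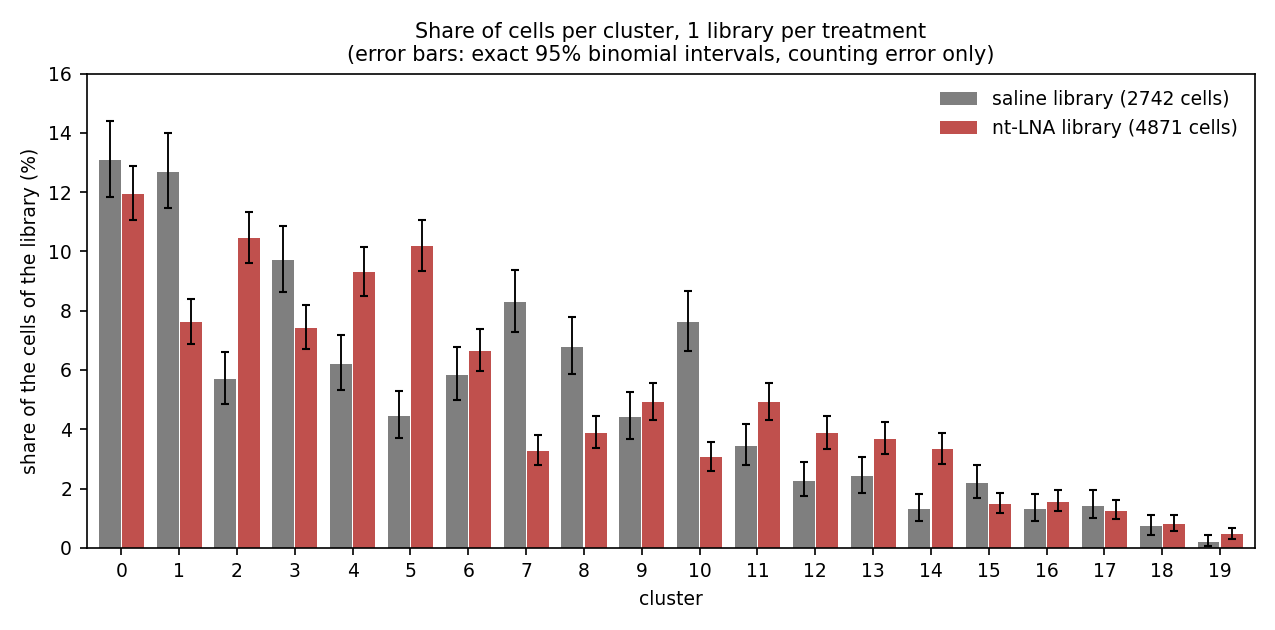
Share of each library's cells (percent, vertical axis) in each of the 20 clusters (horizontal axis), for the saline library (grey) and the nt-LNA library (red); error bars are exact 95% binomial intervals for counting error only. Clusters 7 and 10 hold 8.28% and 7.62% of saline cells but 3.26% and 3.06% of nt-LNA cells, while cluster 5 holds 4.45% and 10.2%.

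Clusters 2, 5, 14 and 16 combined few UMIs with a high share of mitochondrial transcripts. Their cells had a mean of 2296, 1278, 3935 and 1897 UMIs, and 10.1%, 7.24%, 11.2% and 8.42% of these were mitochondrial, against at most 4.29% in every other cluster. Few UMIs did not always go with a high mitochondrial share: cluster 9 had a mean of 3467 UMIs, fewer than cluster 14, but 3.55% mitochondrial. Together clusters 2, 5, 14 and 16 held 12.8% of saline cells (11.5 to 14.1) and 25.5% of nt-LNA cells (24.3 to 26.8). Cluster 5 alone held 4.45% and 10.2%, a ratio of 2.29 (1.87 to 2.81), cluster 2 held 5.69% and 10.4%, and cluster 14 held 1.31% and 3.33%. Cluster 16 differed less, with 1.31% and 1.56% and a ratio of 1.19 (0.789 to 1.82). Without these clusters in the denominator the ratio was 0.462 (0.375 to 0.568) for cluster 7 and 0.470 (0.378 to 0.583) for cluster 10, a choice made after the data were seen. The intervals of clusters 3 (0.764 to 1.06) and 15 (0.554 to 1.13) then held 1, and those of clusters 6 (1.10 to 1.62), 9 (1.04 to 1.63) and 19 (1.07 to 9.81) lay above 1. Shares sum to 100% within a library, so a larger share of one cluster lowers the rest. With 1 library per treatment, differences between libraries have no replicate check and describe these 2 libraries.

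**Figure D2:**
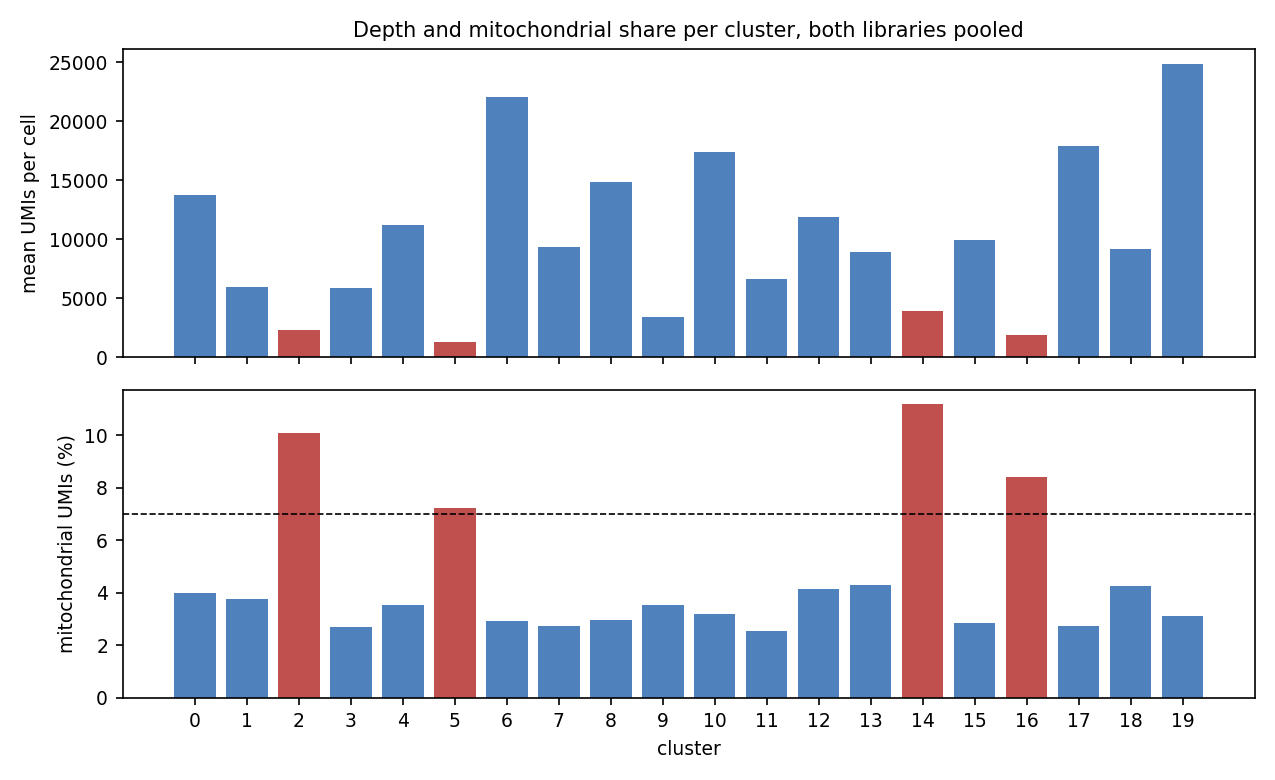
Mean UMIs per cell (upper panel) and percent of UMIs from mitochondrial genes (lower panel) for each of the 20 clusters, both libraries pooled; bars are red where the mitochondrial share exceeds 7% (dashed line). Clusters 2, 5, 14 and 16 lie at 7.24% to 11.2%, and cluster 5 has the fewest UMIs per cell (1278).

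Each myeloid cluster had leading genes of its own, read from UMIs pooled over both libraries. Cluster 10 had the highest Spp1, which encodes the secreted matrix protein osteopontin, at 2360 CPM (2322 to 2399) against a mean of 84.0 in the other clusters. Gpnmb, a lysosome-associated glycoprotein of lipid-laden macrophages, stood at 221 CPM (209 to 233), 23.2 times the other clusters. The monocyte-attracting chemokine Ccl2 stood at 1294 CPM (1266 to 1323), 19.3 times the others, and Vcan, a matrix proteoglycan of monocytes, at 35.8 times. Trem2, a lipid-sensing receptor, was at 122 CPM (113 to 131) in cluster 10 and at 138 CPM (131 to 144) in cluster 0.

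Cluster 7 carried neutrophil genes. Ngp stood at 6181 CPM (6100 to 6262), Camp at 5272 and S100a8 at 43768, the last being 179 times the mean of the other clusters. Il1b, the inflammatory cytokine interleukin 1 beta, was highest there at 3659 CPM (3596 to 3721) and reached 1637 CPM in cluster 8, 1418 in cluster 10 and 1064 in cluster 15. Tnf was at most 105 CPM, also in cluster 7.

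Cluster 0 had 1965 CPM of the complement gene C1qa (1941 to 1990), the alternative-activation gene Retnla at 2336 CPM against a mean of 45.6 elsewhere, and the highest Lyve1, a hyaluronan receptor of resident vessel macrophages, at 22.5 CPM against a mean of 0.813. Its leading genes by ratio also included the smooth muscle genes Myh11 (21.1 CPM) and Cnn1 (8.86 CPM) and the basophil proteases Mcpt8 (45.6 CPM) and Prss34 (68.0 CPM), so the cluster was left unnamed. Cluster 19, 27 cells, had 2070 CPM of C1qa. Its leading genes included Alox15, a lipoxygenase, at 1716 CPM (1618 to 1818), with Prg4 at 2889, Saa3 at 2626 and the chemokine Cxcl13 at 743 CPM. Nonclassical monocyte genes led cluster 15, with Ace at 322 CPM and Cd300e at 291 CPM, 51.3 and 100 times the other clusters. Among dendritic cells, Fscn1 reached 230 CPM in cluster 8, the cross-presentation marker Xcr1 224 CPM in cluster 17 and the plasmacytoid marker Siglech 2200 CPM in cluster 18.

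Among lymphoid clusters, the leading genes of cluster 1 included the follicular B cell genes Fcer2a (319 CPM) and Cr2 (155 CPM), which reached 337 and 178 CPM in cluster 2. Cluster 2 also had the highest Siglecg (736 CPM) and Il5ra (124 CPM), and cluster 4 was led by antibody genes, with Jchain at 2597 CPM and Igha at 1820 CPM. The plasma cell markers Xbp1 and Sdc1 were not among the 50 leading genes of cluster 4. Class II antigen presentation genes had a median log2 ratio of 0.10 there, near the 0.12 of the B cell-like cluster 12. Cluster 3 held 466 CPM of the NK receptor Klra7 and 344 CPM of Ifng. Clusters 11 and 16 had genes of type 2 immunity, with Il5 at 79.4 CPM in cluster 11, and Il13 at 254 CPM and the interleukin 33 receptor Il1rl1 at 1294 CPM in cluster 16. Il17a, a cytokine of type 3 immunity, stood at 53.1 CPM in cluster 11 against a mean of 0.158 elsewhere. Mki67, a proliferation gene, was highest in cluster 14 (2758 CPM, against 783 in cluster 6), and the mitotic gene Ube2c in cluster 6 (665 CPM). CPM is a share of a cluster's UMIs. Ribosomal protein genes took only 9.79% to 11.0% of UMIs in clusters 2, 5, 14 and 16, which can raise the CPM of other genes there. Levels in these clusters therefore compare less directly with those elsewhere.

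**Figure D3:**
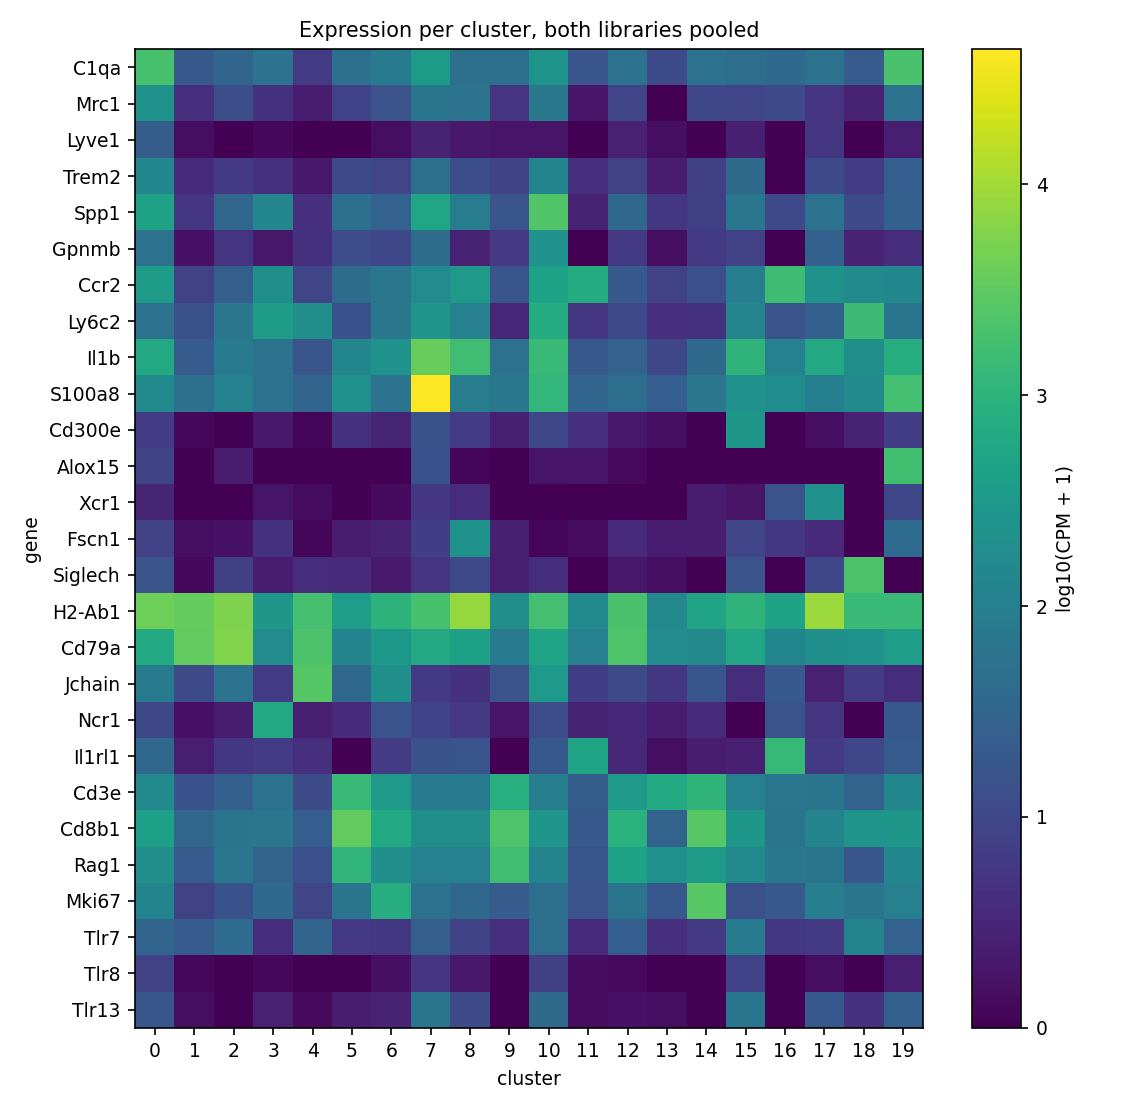
Expression of 27 genes (rows) in the 20 clusters (columns), as log10(CPM + 1) from UMIs pooled over both libraries. S100a8 peaks in cluster 7 (43768 CPM), Spp1 in cluster 10 (2360 CPM), Siglech in cluster 18 (2200 CPM) and Cd8b1 in cluster 5 (3355 CPM).

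Gene lists fixed in advance placed cluster 10 at the high end of several programs. The type I interferon response list had a median log2 ratio of 1.61 there, at the 100th percentile of random lists, with 17 of 25 members over 2-fold higher than the mean of the other clusters and 1 over 2-fold lower. Ifitm3 stood at 3132 CPM (3088 to 3176) against 641, and Ifi204, an interferon-inducible DNA sensor gene, at 259 CPM (247 to 272) against 31.8. Lysosome and cathepsin genes had a median of 1.64, with 16 of 23 members over 2-fold higher, among them Psap at 3255 CPM and Ctss at 2426 CPM. Glycolysis and hypoxia genes had a median of 1.14, with 9 of 17 members over 2-fold higher, and Vegfa stood at 115 CPM against 22.7. For antioxidant and iron genes the median was 1.08, with the ferritin chains Fth1 at 13382 CPM and Ftl1 at 8692 CPM. Lipid droplet and fatty acid genes had a median of only 0.36 (percentile 99.88), near the 0.33 of cluster 7. Of 19 members, 4 were over 2-fold higher in cluster 10 and 2 over 2-fold lower. The liver X receptor and cholesterol efflux list had a median of 0.56, led by Nr1h3, which encodes that receptor's alpha form (46.9 CPM against 8.36), and Npc2 (1126 against 388). Sterol synthesis genes went lower, with a median of -0.68 and Cyp51 at 11.6 CPM against 42.9. Of 19 members, 7 were over 2-fold lower and 2 over 2-fold higher. This was not particular to cluster 10. Among the clusters deposited as Macrophages, medians were lower still in clusters 7 (-1.01), 15 (-0.95), 17 (-0.74) and 19 (-0.75), and higher in clusters 0, 6, 8 and 18.

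In cluster 7 the antioxidant and iron list (median 1.24) and the inflammatory cytokine list (0.85, 14 of 30 members over 2-fold higher) were at the 100th percentile. Examples are the iron exporter Slc40a1 at 51.7 CPM against 1.72, the neutrophil-attracting chemokine Cxcl2 at 4967 CPM against 777, and Il1rn, the interleukin 1 receptor antagonist, at 348 against 30.4. Complement genes had a median of 3.16 in cluster 19, with 10 of 11 members over 2-fold higher, and of 1.26 in cluster 0. Class II antigen presentation genes had medians of 1.60 in cluster 8 and 1.65 in cluster 17, with H2-Ab1 at 8174 and 8824 CPM. Cell cycle genes were over 2-fold higher for 22 of 22 members in cluster 6 (median 2.94) and for 21 of 22 in cluster 14 (1.98). Over the 440 pairs of list and cluster, 102 medians were in the top 2.5% and 207 in the bottom 2.5% of random lists. Against the other clusters deposited as Macrophages, a choice made after the data were seen, the cluster 10 medians were 0.94 for type I interferon, 1.03 for lysosome and 0.84 for glycolysis genes. That reference includes the proliferating-like cluster 6, with medians of -1.97 for type I interferon and -2.07 for lysosome genes, which can raise the values of the others. On that reference antioxidant and iron genes had a median of 0.48 and inflammatory cytokines of 0.72 in cluster 7, complement genes of 0.63 in cluster 0 and 2.31 in cluster 19, and class II genes of 1.42 in cluster 8 and 1.40 in cluster 17.

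Receptors that sense nucleic acids in endosomes differed between clusters, and 2 of them were close to absent. Tlr3, a further receptor of this kind, reached 124 CPM (108 to 142) in the type 1 dendritic cell-like cluster 17, 52.1 times the mean of the other clusters. Tlr7, an endosomal receptor for single-stranded RNA, was highest in the plasmacytoid dendritic cell-like cluster 18 at 118 CPM (90.8 to 151), followed by cluster 15 at 77.7 CPM (63.4 to 94.3) and cluster 10 at 45.9 CPM (40.8 to 51.6). Tlr13, a receptor for bacterial ribosomal RNA, was highest in clusters 15 (63.2 CPM), 7 (59.7 CPM) and 10 (38.5 CPM). Tlr8 had 180 UMIs in all and stood at 7.62 CPM in cluster 15 and 7.39 CPM (5.99 to 9.03) in cluster 0, its highest levels, with 0 UMIs in 8 clusters. Tlr9, a DNA sensor, had 54 UMIs over all clusters and at most 3.27 CPM (1.06 to 7.64, cluster 2), so its order between clusters was not resolved at this depth. The Toll-like receptor pathway as a list had a median of 0.87 in cluster 10 and 0.75 in cluster 15, with the lipopolysaccharide co-receptor Cd14 at 1059 CPM in cluster 10. Against the other clusters deposited as Macrophages the medians were 0.37 and 0.28. Cluster 6, at -2.05, is part of that reference, which can raise these values.

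The Apoe transcript, from the gene disrupted in these mice, gave 420 UMIs in all (5.98 CPM over all clusters). It was highest in cluster 15 at 17.5 CPM (11.1 to 26.3), stood at 13.8 CPM in cluster 7 and 10.8 CPM in cluster 0, and had 0 UMIs in 3 clusters. Tags from the 3' end may lie outside the disrupted part and the counts pool both libraries, so these values check neither library's genotype.

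Ptprc, which encodes CD45, the protein selected for in the sort, was found in every cluster, from 295 CPM (283 to 308) in cluster 4 to 2080 CPM (1981 to 2183) in cluster 5. Cd3e, which encodes a chain of the CD3 complex selected against, reached 1331 CPM (1251 to 1414) in cluster 5, 1100 CPM (1028 to 1176) in cluster 14, 817 CPM (767 to 868) in cluster 9 and 684 CPM in cluster 13. In the B cell-like cluster 1 it stood at 13.8 CPM (10.5 to 17.9), and in the B cell-like cluster 12 at 308 CPM (288 to 328). Clusters 5 and 9 carried T lineage genes, with Cd4 at 839 CPM and Cd8a at 1508 CPM together in cluster 5, and Rag1, a recombinase of immature lymphocytes, at 1657 CPM (1586 to 1730) in cluster 9. Among the leading genes of cluster 13 was Tcrg-C2, a gamma T cell receptor constant gene, at 496 CPM against a mean of 7.33.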

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

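The settings without the high-mitochondrial clusters and without clusters 5, 6, 9, 12 and 14 were chosen only after the data were seen. So were those within the clusters deposited as Macrophages without cluster 6 and with the macrophage reference. Leaving out clusters 5, 6, 9, 12 and 14 keeps cluster 13, which also carried T lineage genes. Leaving the B, T and NK cell clusters out of the denominator multiplies every remaining ratio of shares by the same factor, by construction: it came to 1.28 for cluster 0, 1.60 for cluster 6, 0.555 for cluster 7, 0.805 for cluster 8 and 0.565 for cluster 10. The same values hold where the classes are named and the clusters deposited as Macrophages form the denominator. Without clusters 2, 5, 14 and 16 the ratio was 1.07 for cluster 0 and 0.703 for cluster 1, and without clusters 5, 6, 9, 12 and 14 it was 1.05 for cluster 0. Among the clusters deposited as Macrophages without cluster 6 it was 1.41 for cluster 0, 0.608 for cluster 7, 0.882 (0.717 to 1.09) for cluster 8, 0.619 for cluster 10, 1.04 for cluster 15 and 1.36 for cluster 17. Point values of the other ratios stayed inside the interval first given, but several intervals changed sides of 1. Those of clusters 3 and 15 came to hold 1 without clusters 2, 5, 14 and 16, and again without clusters 5, 6, 9, 12 and 14 (0.750 to 1.04; 0.544 to 1.11), and cluster 15 also in both settings without B, T and NK cell clusters. Cluster 19 came to lie above 1 under these 4 settings, cluster 0 in both without B, T and NK cell clusters, cluster 6 where these alone were left out, and clusters 6 and 9 without clusters 2, 5, 14 and 16. Those of clusters 7 and 10 lay below 1 throughout, and that of cluster 8 except among Macrophages without cluster 6. Of the 200 leading genes (10 per cluster), 192 were shared when scaled by the upper quartile, 117 when the reference was the highest other cluster and 130 with a count minimum of 20; the lower minimum admits genes with fewer counts, and for the highest-cluster reference the cause was not tested. Upper-quartile scaling shifted all genes of a cluster by -0.36 to 0.54 on the log2 scale (-0.10 in cluster 10, 0.07 in cluster 7). Among 198 list medians of the 9 clusters deposited as Macrophages, taking the median of the other clusters as reference changed the sign of 59, 20 of them among the 100 of at least 0.5 in size, and the other clusters deposited as Macrophages changed 44, of which 1 was that large: complement genes in cluster 10, from 0.66 to -0.49. Pairs in the top and bottom 2.5% numbered 102 and 207, 104 and 208 with upper-quartile scaling, 103 and 204 with members of at least 100 counts, and 142 and 142 with the median reference, so the excess of low pairs depends on the reference. Naming clusters by the mean log2 ratio of each marker list turned cluster 10 from foamy macrophage-like into classical monocyte-like and would have named clusters 0 (smooth muscle), 19 (inflammatory macrophage), 2, 5, 9, 13 and 14. Other scalings and count minimums intended for gene expression between treatments were not run, because the counts pool both libraries. No paired analysis was possible because each treatment had 1 library.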

Other observations

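The 4 clusters with few UMIs and a high mitochondrial share had the highest Xist and the fewest ribosomal protein transcripts. Malat1, a nuclear long non-coding RNA, made up 11.6% of UMIs in cluster 5, 9.45% in cluster 2 and 7.29% in cluster 16, but only 3.88% in cluster 14, less than in clusters 9, 12 and 18, and was lowest in cluster 6 at 1.30%. Xist, the non-coding RNA of the inactive X chromosome, stood at 6955 CPM in cluster 14, 4362 in cluster 5, 4193 in cluster 16 and 3723 in cluster 2, with its lowest level, 728 CPM, in cluster 7. Ribosomal protein genes took 9.79% to 11.0% of UMIs in these 4 clusters and 36.6% in cluster 4. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 UMIs in both libraries together, where 3 UMIs would be 0.0427 CPM. In cluster 19, Gata6, a transcription factor of serous cavity macrophages, stood at 31.3 CPM (19.4 to 47.8) against a mean of 0.263 elsewhere.

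In cluster 16 the class I antigen presentation genes had a median log2 ratio of 1.31, with H2-Q7 at 1779 CPM against 349, and the immediate-early gene Fosb reached 3082 CPM against 287. The heat shock and immediate-early list had a median of 0.46 there, with 7 of 22 members over 2-fold higher and 4 over 2-fold lower. In cluster 11 its median was 1.07, with 12 members over 2-fold higher and 3 over 2-fold lower.

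Of the tests below, those of both dilution explanations, of free RNA, of droplets with a B cell and a T lineage cell, and of the rise in cluster 12 relative to clusters 3 and 9 were chosen only after the result was seen. Clusters 7 and 10 held smaller shares of the nt-LNA library. Dilution by cells with few UMIs and a high mitochondrial share is argued against as the whole cause. Without clusters 2, 5, 14 and 16 the higher of the 2 upper bounds of the ratio was 0.583. Dilution by lymphocytes and cycling cells is argued against as the whole cause likewise, since among the clusters deposited as Macrophages without cluster 6 that bound was 0.767; the ratios themselves came nearer 1 there, from 0.394 to 0.608 and from 0.401 to 0.619, so part of the difference goes with the denominator. Both bounds follow from the shares given above by a fixed factor per setting, so they restate these shares and are not independent tests. Clusters 7 and 10 were also the clusters with the lowest ratios in the same shares. An effect of nt-LNA and a difference between animals or libraries cannot be told apart with 1 library per treatment, and the first was not tested.

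Cluster 12 held B cell and T cell genes together. Over cluster 1, T lineage genes stood there at a median of 15.6 times (11.2 to 22.2), myeloid genes at 1.82 to 2.88 times and neutrophil genes at a median of 0.914 times (0.574 to 4.59), so that the T lineage median was 5.59 and 17.1 times theirs (16.3 for neutrophil genes with at least 20 UMIs), which free RNA from all cells would not give. The NK cell median was 0.214 of the T lineage median but rested on genes with few UMIs; of those with at least 20 UMIs, Gzma stood at 10.6, Ccl5 at 2.31 and Nkg7 at 1.13 times, a rise of at most 0.797% of their level in cluster 3, against 29.3% to 41.5% of the level in cluster 9 for T lineage genes, which argues against chance pairs of B cells with every cell type. Droplets with a B cell and a T lineage cell stay possible. Cells of cluster 12 had a mean of 11884 UMIs, against 5925 in cluster 1 and 2296 in cluster 2. This was only 1.06 times the mean of the plasma cell-like cluster 4, and no spread between cells was at hand to judge that. Each of the 10 leading genes of cluster 12 stood higher in another cluster, and the largest ratio was 3.27 (Sox5). Such droplets would give these levels, but this was seen after the result and was not tested. No biological explanation was tested.

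Clusters 5, 9 and 14 held CD3 genes in a sort for cells without CD3. Free RNA is argued against, as Cd3e stood in each of them at 59.0 times its level in cluster 1 or more. These Cd3e levels are among those that raised the question, so this is a reading of them and not an independent test. A candidate explanation is immature T cells of the thymus, which carry little CD3 on their surface and lie near the aortic arch, and which a CD3 sort could miss; the labels name no thymus. Of 6 genes written down before their values were seen (Rag2, Ptcra, Dntt, Arpp21, Cd8b1 and Aqp11), 4 stood in cluster 5 and 6 in cluster 9 at 5 times the median of the clusters other than 5, 6, 9, 12 and 14 or more, with Cd8b1 at 3355 and 2332 CPM; Dntt and Ptcra did not in cluster 5. The smaller number, 4, argues against mature T cells that passed the sort, for which fewer than 2 were foretold; clusters 6, 12, 13 and 14 reached 6, 4, 5 and 5 of the genes and every other cluster 0.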
